A study of Drosophila melanogaster with 34 samples.

How the data were processed

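The samples were grouped by the antibody, stage or cell line and title that the submitters gave. Per the labels' protocols material was fixed with 1.8% formaldehyde, per the series record the ChIP and input DNA was sequenced as 36 bp reads, and per the submitters' processing notes the coordinates are on release 5 of the BDGP genome. The ChIP samples made against GFP came from flies carrying a GFP-tagged protein in another strain background than their inputs, per the labels' protocols. The aligner and the peak caller, with their settings and versions, are not given in the sources used here. Per the titles, the authors pooled the numbered libraries of a sample, 1 to 3 per list, before deposit, so regions per library were not compared.

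The authors deposited 2 kinds of list. In 15 of them each peak had a chromosome, start and end and no height, fold or p, so peaks were ranked by width where a rank was needed. In the other 3 (both EcR lists and Caudal L3 larvae) each region also had a score, and per the file headers the regions were cut from a density track with a count threshold of 310.4 for EcR at 30 to 33 h, 169.4 for EcR at 10 to 11 h and 133.8 for Caudal L3, a maximum gap of 100 bp and a minimum run of 100 bp. The scale of the authors' score is not stated. Its lowest value in each list lies just above log2 of the threshold (8.32 against 8.28, 7.41 against 7.40 and 7.07 against 7.06), and it was used only to rank regions within a list. The header of the Caudal L3 list carries a track name with EcR in it, which differs from the labels; the labels were followed. The 3 lists with a score held 483 to 603 regions with median widths of 235 to 435 bp, and the others 989 to 5627 peaks with median widths of 973 to 5826 bp, so lists of the 2 kinds differ in how they were made as well as in target.

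Regions on the arms 2L, 2R, 3L, 3R, 4 and X were analysed, with the lowest start and highest end over all lists taken as the extent of an arm (120102709 bp in all). No list had regions that overlapped one another. In all, 5 peaks had a start below 0 and were used as given. Regions were shared when they overlapped by 1 bp or more, and the overlap of 2 lists was the share of peaks in the shorter list that overlapped the longer one, with a 95% Wilson interval that covers counting error only. Chance came from placing the peaks of the shorter list at random within their arms, 10000 times for the planned pairs and 1000 times for all 153 pairs. These one-sided permutation tests treat peaks as independent and compare lists, not conditions. The HDAC lists were tested by an exact permutation over every division of the 10 lists into pairs. Shares of arms were tested by exact binomial tests, two-sided. Benjamini-Hochberg adjustment was made over the 6 Caudal pairs, over all 153 pairs and over all tests of a list and an arm, and 0.05 was the threshold throughout. Nothing in the labels says that lists of 1 target came from separate collections of embryos or cells, so the spread between them may be technical. All HDAC lists share 1 input library, and the overlap between them was not corrected for it.

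The tests, alternatives and rule for naming regions were fixed before the data were examined. The rule named the 5 highest regions per list (per HDAC, regions in both of its lists ranked by mean rank) and the 10 merged regions present in the most lists, by coordinates where no annotation of the build was at hand; of these the text gives the leading ones. The gene table used here is of release 6 and holds no sequence, so the planned tests of promoter shares, fixed gene lists, sequence motifs and the tagged gene loci were not run. Segments of dense binding were described after the counts had been seen. Alternatives were a 50% overlap of the smaller peak, midpoints within 250 bp, the Jaccard index of base pairs, the upper 50% of each list, equal numbers of peaks per list (982), a circular shift of a whole list as the chance level, leaving out each HDAC list, and all sequences of the build.

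The overlap test was tested on simulated lists drawn with the number, widths and arms of the deposited ones. Simulated peaks that overlapped the one before were then dropped, so these lists could hold fewer peaks than the numbers given here. With no peaks placed on the other list it passed the threshold in 2 of 100 runs laid out as the CTCF pair (2615 peaks), 7 of 100 as the Caudal embryo pair (2159 peaks) and 3 of 100 as the EcR pair (478 regions). With 10% of peaks placed on the other list it passed in 20 of 20 runs for each pair and recovered 9.66%, 9.49% and 9.66%. With 40% placed it passed in 20 of 20 runs for each pair and recovered 37.0%, 37.0% and 35.1%. Apart from the placed peaks, both lists were drawn at random as in the overlap test itself. These runs therefore lack clusters of peaks and chromatin common to many lists, and do not give the error rate on the deposited lists. The exact test of HDAC pairs passed in 0 of 20 runs with no shared peaks and in 20 of 20 with 30% placed. In these runs lists of different targets shared peaks only through random placement. Deposited lists of different targets overlapped at 42.9% on average, so the runs do not give the power of the exact test there. Computations used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.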

Results

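Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where 8 proteins of Drosophila melanogaster lie along the genome. These were 5 histone deacetylases (HDAC1, HDAC3, HDAC4a, HDAC6 and HDAC11, enzymes that remove acetyl groups from histones and other proteins), the insulator protein CTCF, the homeodomain transcription factor Caudal, which patterns the posterior embryo, and the ecdysone receptor EcR, a nuclear receptor for the moulting hormone. The series held 34 samples, of which 16 were inputs without a list of their own and 18 were ChIP samples with 1 list of bound regions each. Every HDAC had 2 lists from embryos of 0 to 12 h, called list 1 and list 2 here in the order of the numbers in their titles, which run from 492 for HDAC4a to 501 for HDAC1. CTCF had 2 lists from S2 cells, an embryo-derived cell line, carrying the numbers 200 and 500. Caudal had 1 list at each of 4 stages, namely embryos of 0 to 4 h, embryos of 4 to 8 h, L3 larvae and adult females of 21 days. EcR had 1 list at 10 to 11 h and 1 at 30 to 33 h, both labelled WPP, for white prepupae. A list pooled 1 to 3 libraries, so each was a single observation without replicate error. The Caudal lists of 4 to 8 h embryos and adult females came from 1 library each.

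The lists held 48602 regions in all, and 48081 of these lay on the arms 2L, 2R, 3L, 3R, 4 and X. The number per list ran from 483 for EcR at 30 to 33 h to 5627 for Caudal in 4 to 8 h embryos. Median widths ran from 235 bp in the Caudal L3 list to 5826 bp in HDAC3 list 2, and the covered share of the arms from 0.113% to 15.8% in the same 2 lists. No list gave a read count, so the depth behind each region is unknown. All coordinates are 1-based positions on release 5 of the genome, and no gene was assigned to any region.

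HDAC3 and HDAC1 had the highest overlap between their own lists among the 5 deacetylases. Of the 2552 peaks in HDAC3 list 2, 90.4% (95% Wilson interval 89.2% to 91.4%) overlapped a peak of HDAC3 list 1, and 85.4% (84.1% to 86.6%) of the 2998 peaks in HDAC1 list 1 overlapped HDAC1 list 2. The corresponding share was 47.8% (46.0% to 49.6%) for HDAC6, 28.5% (26.8% to 30.2%) for HDAC4a and 19.1% (16.8% to 21.7%) for HDAC11. Since the lists cover different lengths, the shares were also set against random placement. The order then changed in part, with a fold of 4.02 for HDAC1, 3.60 for HDAC3, 2.74 for HDAC6, 2.19 for HDAC11 and 1.92 for HDAC4a. Random placement itself gave 21.3%, 25.1%, 17.5%, 8.73% and 14.9% in the same order. A higher chance share lowers the highest fold possible, so the order by fold depends on coverage as well. Some lists matched another deacetylase more closely than their own partner. The HDAC6 list 1 overlapped HDAC4a list 2 at 83.6% of its peaks, with 37 intervals identical to the base pair, whereas the 2 lists of each deacetylase had no identical interval. HDAC6 list 2 overlapped HDAC1 list 1 at 82.0% and HDAC1 list 2 at 72.1%. The shares of HDAC6 and HDAC4a therefore rest on labels that were taken as given.

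Whether lists of one deacetylase overlapped more than lists of different ones was tested over all 945 divisions of the 10 lists into 5 pairs. The mean overlap was 54.2% for the pairs with the same target and 42.9% for pairs with different targets, and 79 of the 945 divisions gave a mean as high, so the excess did not pass the threshold (one-sided exact permutation test, p = 0.084). The best match of a list had the same target in 4 of 10 lists. The outcome depended on the setting: the exact p was 0.056 with 50% of the smaller peak and 0.1 with the upper 50% of each list, but 0.046 with midpoints within 250 bp, 0.021 with the Jaccard index of base pairs and 0.018 with equal numbers of the widest peaks. Leaving out 1 list gave an exact p of 0.36 to 0.37 without an HDAC3 list, 0.23 to 0.29 without an HDAC1 list, 0.021 without HDAC4a list 2, 0.028 without HDAC11 list 1 and 0.052 to 0.074 without any other, so the excess rested on HDAC3 and HDAC1. All 10 lists were made against the same input library, which could not be split.

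**Figure D1:**
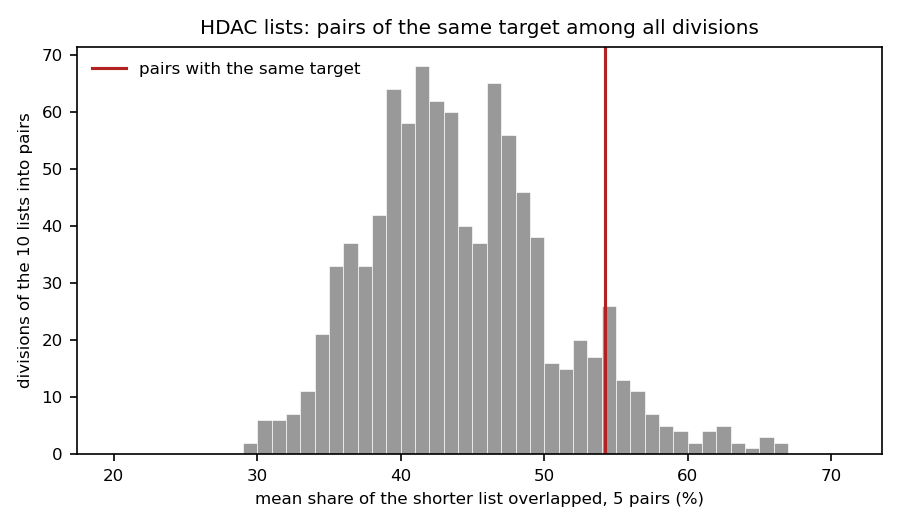
Mean share of the shorter list overlapped (%, horizontal axis) over each of the 945 divisions of the 10 HDAC lists into 5 pairs, with the number of divisions on the vertical axis. The red line marks the division by target at 54.2%, and 79 divisions lie at or above it.

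The regions held by both lists of a deacetylase were shared with other deacetylases more often than by chance. Of the 1413 HDAC6 peaks found in both HDAC6 lists, 99.6% overlapped a list of another deacetylase, against 45.7% when these peaks were placed at random. The share was 94.1% against 43.3% for HDAC1, 86.1% against 53.5% for HDAC3, 94.7% against 40.3% for HDAC4a and 89.9% against 50.1% for HDAC11 (one-sided permutation tests by random placement, chosen after the result was seen, p = 0.001 each, the smallest that 1000 draws can give). Peaks overlapping all 4 of the other deacetylases made up 11.8% of the HDAC1 regions and 35.6% of the HDAC11 regions, against 3.14% and 8.94% by chance. All these shares count the closely matching lists of different labels. HDAC4a list 2 overlapped 83.6% of HDAC6 list 1, and HDAC6 list 2 overlapped 82.0% of HDAC1 list 1. The shares of HDAC6, HDAC4a and HDAC1 in particular may therefore reflect these matches, and random placement does not allow for them. The highest-ranked HDAC3 region lay at 3R 1398513 to 1442331 and reached 36748 bp and 43819 bp in the individual lists. The highest-ranked HDAC1 region lay at 3L 19143976 to 19179132, that of HDAC4a at 2L 19121972 to 19140133, that of HDAC6 at 2L 19570499 to 19588400 and that of HDAC11 at 2R 7902196 to 7920885. The HDAC11 region carried a peak in all 10 HDAC lists, as did the HDAC11 regions at 3R 1287183 to 1303953 and 2R 19587037 to 19602239.

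Most CTCF sites of the shorter S2 list recurred in the longer one, which held many more. Of the 2615 peaks in the CTCF 500 list, 2401 (91.8%, interval 90.7% to 92.8%) overlapped one of the 4879 peaks in the CTCF 200 list, against 10.4% under random placement. This was an 8.87-fold excess (one-sided permutation test by random placement, p = 0.0001, the smallest that 10000 draws can give). Conversely, 49.8% of the CTCF 200 peaks overlapped the shorter list, and 2449 did not. The widest CTCF 500 peak, at 3L 16399806 to 16406088, coincided with the CTCF 200 peak of rank 2 at 3L 16399816 to 16406920. The widest CTCF 200 peak lay at 3R 12082362 to 12090832 and was also covered in the CTCF 500 list.

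Caudal sites in early embryos recurred in adult females more than in the 4 to 8 h embryos that follow. Of the 2159 peaks of 0 to 4 h embryos, 609 (28.2%, interval 26.3% to 30.1%) overlapped an adult female peak, 3.17-fold over random placement (permutation test, p = 0.0001, adjusted p = 0.0003 over the 6 pairs of stages). The L3 list overlapped the adult female list 2.17-fold (adjusted p = 0.0003), the 0 to 4 h list 1.62-fold (adjusted p = 0.0032) and the 4 to 8 h list 1.28-fold (adjusted p = 0.021), all by the same permutation test. In contrast, 297 of the 2159 early peaks (13.8%, interval 12.4% to 15.3%) overlapped the 4 to 8 h list against 18.7% by chance, 0.736-fold, and the adult female and 4 to 8 h lists overlapped 0.809-fold. Both lay under chance in the lower tail of the permutation test (adjusted p = 0.0003), a test chosen after the result was seen. With midpoints within 250 bp in place of any overlap, the early and 4 to 8 h lists stood at 1.48-fold (permutation adjusted p = 0.004) and the adult and 4 to 8 h lists at 1.02-fold (permutation adjusted p = 0.44), while with 50% of the smaller peak (0.833-fold and 0.787-fold), the upper 50% of each list (0.833-fold and 0.709-fold) and a circular shift (0.738-fold and 0.809-fold) both stayed under chance. With midpoints the 2 embryo lists no longer passed the threshold against the L3 list. Their folds stayed above 1, at 1.74 and 1.44 on 9 and 20 shared regions (permutation adjusted p = 0.096 each). Antibody differed with stage, being against Caudal for the 0 to 4 h list and against GFP for the others.

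Few regions of the L3 list, the shortest and narrowest of the Caudal lists, lay in every other Caudal list. Of the 584 L3 regions, 434 overlapped no other Caudal list, 126 overlapped 1, 23 overlapped 2, and 1 overlapped all of them. In all, 150 overlapped another Caudal list, against 104 by random placement. No chance level was computed for the number in every list. Of the 2159 peaks of 0 to 4 h embryos, 105 overlapped both the 4 to 8 h and the adult female lists. The widest peaks of 0 to 4 h embryos lay at 2R 5856322 to 5877366, 2L 20767077 to 20788098 and 3R 6415372 to 6432500. The region on 2R carried peaks in 12 of the 18 lists, among them 8 HDAC lists, both CTCF lists and the 4 to 8 h Caudal list. The widest peak of 4 to 8 h embryos, at 3L 1759053 to 1771284, was otherwise covered only in the HDAC3 lists. The L3 region of the highest score (8.68) lay at 2L 15911299 to 15912133, within an EcR region. The widest adult female peak lay at 2L 2749211 to 2755948.

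One segment of 3R stood out in early embryos. Between 12.5 and 12.8 Mb the 0 to 4 h Caudal list had 58 peaks, against 5.39 by length, and these covered 58.5% of the segment. HDAC4a list 2 had 54 peaks there and HDAC4a list 1 had 16, and HDAC6 list 1 had 48 and HDAC6 list 2 had 18, so the dense lists were the closely matching pair of different targets. By length, 10.0 and 6.75 were expected for the HDAC4a lists and 7.38 and 8.69 for the HDAC6 lists. CTCF 200 had 36 peaks against 12.2 and CTCF 500 had 23 against 6.53. HDAC3 had 1 peak in list 1 and 0 in list 2. The later Caudal lists showed no excess, with 14 peaks at 4 to 8 h against 14.0 by length, 0 in L3 larvae against 1.46 and 5 in adult females against 8.51. The segment was chosen after the counts had been seen.

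**Figure D2:**
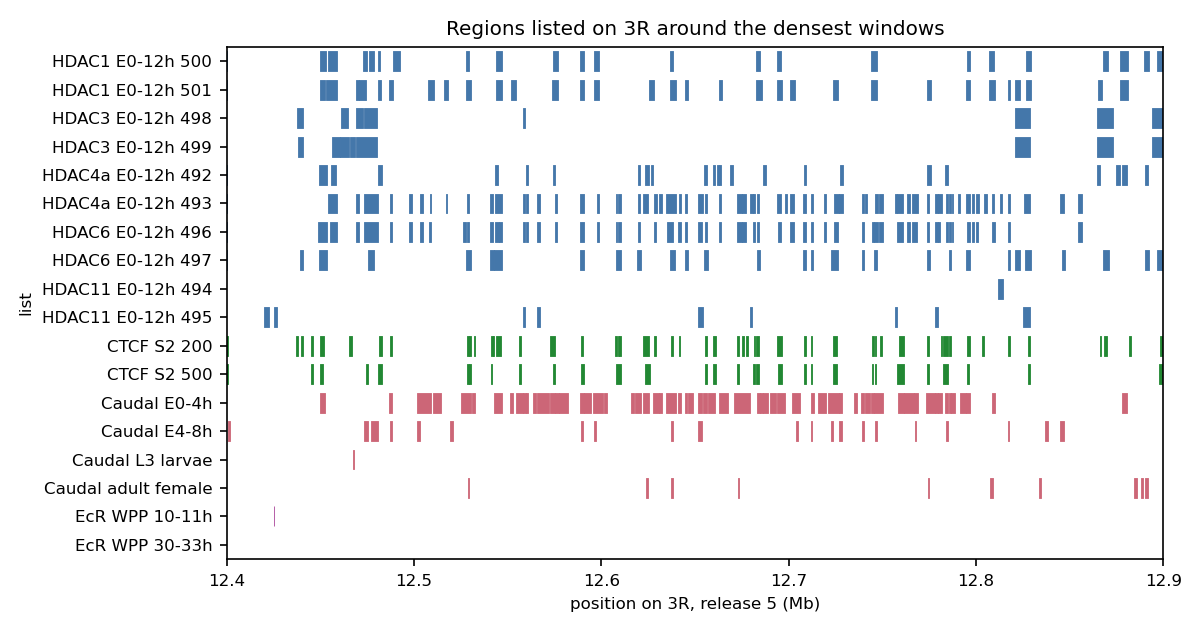
Map of the regions in each of the 18 lists (rows) along 3R around 12.5 to 12.8 Mb (horizontal axis, position in Mb on release 5), with HDAC lists in blue, CTCF in green, Caudal in rose and EcR in purple. The Caudal list of 0 to 4 h embryos fills 58.5% of the segment between 12.5 and 12.8 Mb, and the HDAC3 and EcR lists are almost empty there; of each HDAC, the list with the lower number is list 1.

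EcR occupied many of the same regions at both times. Of the 478 regions on the arms at 30 to 33 h, 255 (53.3%, interval 48.9% to 57.8%) overlapped one of the 483 regions at 10 to 11 h, against 0.460% by chance. The excess was 116-fold (one-sided permutation test by random placement, p = 0.0001, the smallest that 10000 draws can give), and 223 regions at 30 to 33 h and 227 at 10 to 11 h had no counterpart. The region of the highest score at 10 to 11 h, 2L 15910641 to 15912775, scored 10.2, and that at 30 to 33 h, 2L 6078614 to 6079548, scored 11.0; each lay in both lists. Others among the 5 highest at 10 to 11 h, all bound at both times, were 3L 17964109 to 17966843, 2L 2201741 to 2203875 and 3L 17957409 to 17958943. Of the 5 highest at 30 to 33 h, 3L 17979162 to 17980196, of score 10.6, was the only one without a counterpart at the other time. The scores are the authors' own and were not compared between the lists, whose thresholds differed.

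A cluster on 3L held the densest EcR binding. Between 17.9 and 18.1 Mb there were 26 regions at 10 to 11 h and 29 at 30 to 33 h, against 0.804 and 0.796 by length. Of the 5 highest-scoring EcR regions, 2 lay in this cluster at 10 to 11 h and 4 at 30 to 33 h. The adult female Caudal list had 17 peaks in the segment against 5.67 by length, HDAC1 list 2 had 10 against 6.84, CTCF 200 had 9 against 8.12 and CTCF 500 had 8 against 4.35. HDAC1 list 1 had 6 against 4.99, HDAC6 list 2 had 7 against 5.79 and the Caudal L3 list had 3 against 0.973. All remaining lists lay below the number by length. Among them, each HDAC3 list had 1 peak, against 4.34 and 4.25. HDAC6 list 1 had 2 against 4.92, and Caudal at 0 to 4 h had 2 against 3.60. Arm 3L as a whole carried 27.5% of the EcR regions at 10 to 11 h and 30.3% at 30 to 33 h, against 20.4% of bases (exact binomial tests, two-sided, adjusted p = 0.0013 and 3.8e-06). Without the cluster, a setting added after seeing the data, the shares were 23.4% (exact binomial p = 0.12) and 25.8% (exact binomial p = 0.0058).

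**Figure D3:**
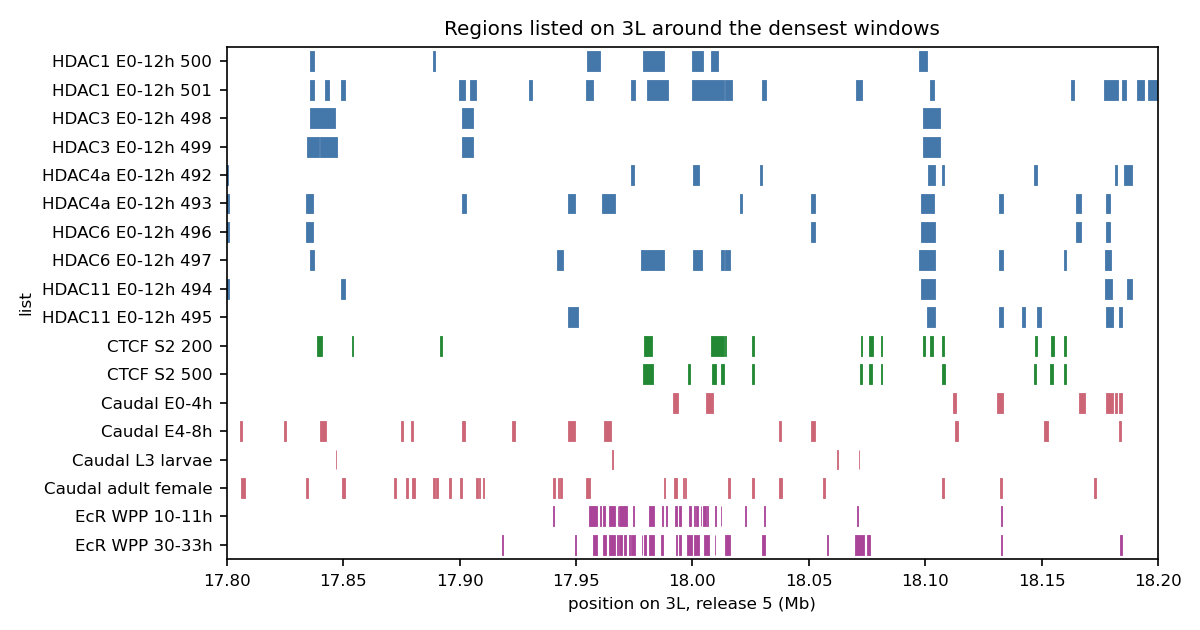
Map of the regions in each of the 18 lists (rows) along 3L around 17.9 to 18.1 Mb (horizontal axis, position in Mb on release 5), coloured as HDAC in blue, CTCF in green, Caudal in rose and EcR in purple. The EcR lists hold 26 and 29 regions between 17.9 and 18.1 Mb.

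Regions of different proteins overlapped in most pairs of lists. Among the 140 pairs of lists with different targets, 123 overlapped more than under random placement and 3 less (permutation tests with 1000 draws, adjusted over 153 pairs), with a median of 2.08-fold. The folds ran from 0.576 for EcR at 10 to 11 h with HDAC11 list 2 to 14.0 for EcR at 10 to 11 h with Caudal in L3 larvae. EcR regions at 10 to 11 h exceeded chance 6.99-fold with the adult female Caudal list and 3.56-fold and 3.66-fold with the HDAC1 lists, and stood at 1.06-fold and 1.02-fold with the HDAC3 lists. CTCF 200 stood at 3.31-fold and 2.76-fold with the HDAC1 lists and at 2.56-fold and 3.23-fold with the HDAC6 lists. The 3 pairs under chance were the Caudal list of 0 to 4 h embryos with HDAC3 list 1 (0.758-fold), HDAC3 list 2 (0.769-fold) and HDAC11 list 2 (0.658-fold). With the upper 50% of each list by rank, 126 pairs lay above chance and 0 passed below it. There the early Caudal list stood at 1.12-fold and 1.02-fold with the HDAC3 lists and at 0.726-fold with HDAC11 list 2, and calls below chance rested on the smallest p that 1000 draws can give (permutation adjusted p = 0.031).

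**Figure D4:**
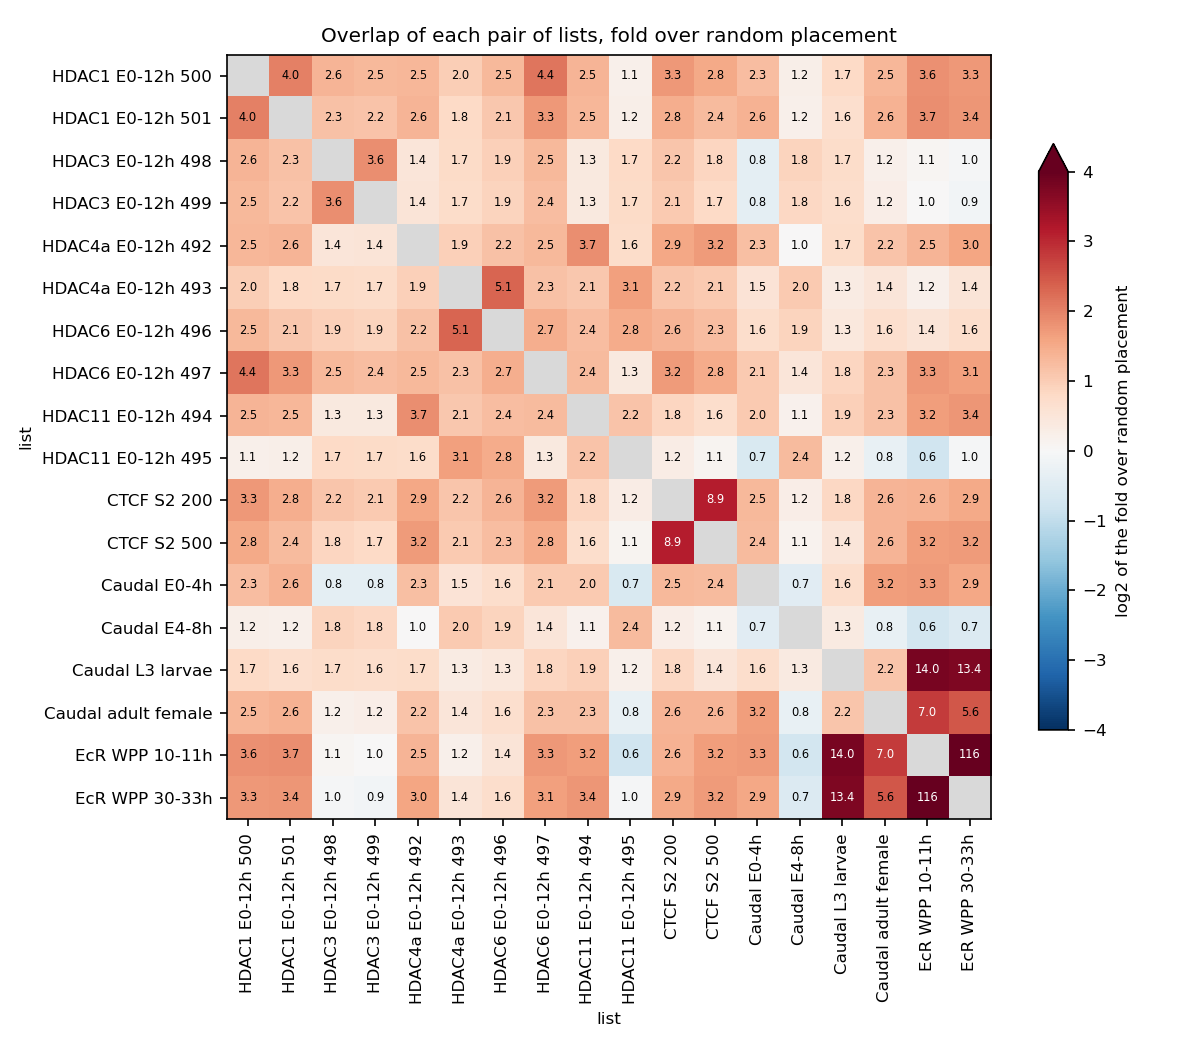
Overlap of every pair of the 18 lists as the fold over random placement (numbers in the cells; colour gives its log2, with values above 4 shown at the end of the scale). The EcR pair stands at 116, the CTCF pair at 8.85 with 1000 draws, and the Caudal L3 list reaches 14.0 and 13.4 with the EcR lists.

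The X chromosome held different shares of the peaks from list to list. It held 18.7% of the bases of the arms but 11.9% (interval 10.6% to 13.3%) of the Caudal peaks at 0 to 4 h, 12.7% (11.9% to 13.6%) at 4 to 8 h and 13.5% (11.0% to 16.5%) in L3 larvae (exact binomial tests, two-sided, adjusted p = 1.2e-15, 1.9e-30 and 0.0041). The adult female share was 17.4% and did not pass the test. HDAC11 list 1 had the highest X share, 27.5% (24.8% to 30.4%, exact binomial, adjusted p = 2.6e-10), while HDAC11 list 2 had 19.3% and did not pass. HDAC4a list 2 (920 of 4003 peaks), the HDAC3 lists (21.4% and 20.8%), the HDAC6 lists (20.9% and 20.6%) and the CTCF lists (20.7% and 20.5%) also passed above the share of bases, and HDAC1 list 2 (16.9%) and EcR at 30 to 33 h (12.3%) passed below it. Chromosome 4, with 1.00% of the bases, held 1.96% and 1.84% of the HDAC3 peaks (exact binomial, adjusted p = 0.00013 and 0.00096). It also held 1.56% of the peaks of HDAC1 list 2 (exact binomial, adjusted p = 0.0035). In contrast, it held 0.107% of the Caudal peaks at 4 to 8 h (exact binomial, adjusted p = 1.2e-15) and none of the EcR regions on the arms. Both HDAC4a lists, HDAC6 list 2 and HDAC11 list 2 also passed below its share of bases. Of the tests of each list on each arm, 45 passed, 25 with more and 20 with fewer peaks than the share of bases, and 63 did not. When heterochromatic and unplaced sequences were added, which lowers the expected share of every arm, 89 passed.

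Merging all lists gave 12519 regions, of which 5295 came from 1 list, 4 were present in 17 of the 18 lists and 0 in all 18. The 4 regions lay at 2L 2133946 to 2205478, 2L 19561956 to 19588590, 2L 466399 to 494713 and 3L 3042097 to 3061631. The first lacked a peak in HDAC11 list 2, the third in HDAC6 list 1, and the remaining ones in the Caudal L3 list. A further 9 regions were present in 16 lists, the highest-ranked being 2L 11999773 to 12022263, 3L 14760473 to 14796568, 3R 8819874 to 8855616, 2R 12064898 to 12091081, 2R 3945738 to 3975938 and 3R 12072427 to 12109519. Merging joins neighbouring peaks, so these regions, 19535 to 71533 bp wide, need not be bound at the same bases in each list.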

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

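Regions on the mitochondrial genome were outside the comparisons. They appeared in 4 of the 18 lists, above the limit of 3 that a count of 0 allows: 11 in the Caudal list of adult females, 11 in that of 0 to 4 h embryos, 6 in that of L3 larvae and 5 in the EcR list at 10 to 11 h. The other 14 lists had 0. No explanation was tested.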

How the results depend on the processing

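The fold over chance for HDAC lists, the lower tail for Caudal lists, the EcR share of 3L without its cluster and the L3 overlap without the highest scores were tests chosen after the result was seen. Of 57 alternative values, 45 kept their direction and side of the threshold, among them all 4 alternatives of the CTCF pair and all 4 of the EcR pair. For the HDAC lists, the mean overlap of lists with the same target was 26.5% with midpoints within 250 bp (p = 0.046), 34.7% with the Jaccard index of base pairs (p = 0.021) and 44.0% with equal numbers of the widest peaks (p = 0.018), each past the threshold of the exact permutation test that the reported value missed; the cause was not tested. Leaving out each list in turn gave 45.2% to 63.0%, with exact p of 0.021 to 0.37, and it passed only without HDAC4a list 2 or HDAC11 list 1 and lay highest without an HDAC3 list. With midpoints, the Caudal lists of 0 to 4 h and 4 to 8 h rose from under chance to 1.48-fold (permutation adjusted p = 0.004), those of 4 to 8 h and adult females no longer differed detectably from chance at 1.02-fold (permutation adjusted p = 0.44), and the L3 list with the 0 to 4 h and 4 to 8 h lists, at 1.74-fold and 1.44-fold, no longer passed; the cause was not tested. With the upper 50% of each list, 0 pairs of different targets passed under chance; the folds of the 3 pairs became 1.12, 1.02 and 0.726 on fewer peaks, and so few pairs cannot pass after adjustment with 1000 draws unless several reach the smallest p. With all sequences of the build, 89 tests of arms passed, by construction since every expected share fell. The EcR share of 3L at 10 to 11 h fell to 23.4% without the cluster (exact binomial p = 0.12). No paired analysis was possible because each list pools its numbered libraries and the inputs of the same numbers have no list. Promoter, gene list and motif alternatives were not run for want of a matching annotation. Depth limits were not examined, since no read count was given.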

Other observations

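The exact permutation test of the HDAC pairs and the overlap of each pair of lists were planned. Every other test in this part was chosen after the result was seen. The use of pair overlaps to weigh explanations, with the choice of pairs for each explanation, also came after the result was seen. EcR regions found at both times scored higher than those found at one. Because both lists were cut at a threshold, the test cannot tell this apart from regions near the cut being missed at the other time. At 10 to 11 h the median score was 8.10 in the 256 shared regions and 7.61 in the 227 others, and at 30 to 33 h it was 8.88 in the 255 shared regions and 8.62 in the 223 others (two-sided permutation tests, p = 1e-05 each, the smallest that 100000 permutations can give). Of the 50 highest regions, 49 at 10 to 11 h and 43 at 30 to 33 h were shared. A smaller EcR cluster lay at X 1.8 to 1.9 Mb, with 11 regions at each time against 0.402 and 0.398 by length.

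Some deacetylase lists were dense at 2L 10.2 to 10.45 Mb, where HDAC3 list 1 had 36 peaks against 5.42 by length and HDAC3 list 2 had 31 against 5.31, covering 63.6% and 72.1% of the segment. As fold over that expected by length, the HDAC1 lists stood at 4.17 and 3.98, the HDAC4a lists at 4.26 and 1.32, the HDAC6 lists at 1.46 and 2.49 and the HDAC11 lists at 1.47 and 3.51. In the 100 kb windows with the most regions, HDAC3 list 1 had 15 peaks at 2L 10200001 to 10300000 and EcR had 24 regions at 10 to 11 h at 3L 17950001 to 18050000, each above every one of 1000 random placements (permutation p = 0.001, the smallest they can give). Bases covered by at least 5 of the 10 HDAC lists came to 6655 kb, against 97.6 kb on average over 100 random circular shifts. Each list was shifted separately, so this chance level also lacks the overlap between the 2 lists of a deacetylase. The 5 lists need not stand for 5 deacetylases.

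Deacetylase lists shared regions across targets. That these lists hold nothing but noise particular to the 1 embryo input was argued against by the CTCF 200 list, which has another input. Its overlap with every HDAC list exceeded chance, the lowest being 1.23-fold. With CTCF 500 this held for 9 of the 10 lists and not for HDAC11 list 2 (1.09-fold, permutation adjusted p = 0.16). Whole lists were compared, so this does not bear on the source of the regions that deacetylases share with one another. Background that recurs in several inputs would also exceed random placement, so the overlap with CTCF cannot exclude it. Whether the shared input or open chromatin picked up by every ChIP accounts for the sharing cannot be told apart from target-specific binding. The exact permutation p of 0.084 met what that explanation predicts, but other overlap measures fell under 0.05, and part of the excess may come from the shared input. A wrong label on HDAC6 list 2 also stays open. The lower overlap of this list with the 2 HDAC1 lists was 24.3 percentage points above that with HDAC6 list 1. Only 4 of the 10 lists had their best match within their own target, so the rank alone does not single this list out. By the Jaccard index of base pairs it stood at 53.4% with HDAC1 list 1, above the 47.6% of the HDAC1 pair, with 5 identical intervals. HDAC4a list 1 and the HDAC11 lists reached only 17.4%, 13.6% and 16.9% with their best matches. The X share of HDAC6 list 2 (20.6%) lay nearer HDAC6 list 1 (20.9%) than the HDAC1 lists (17.5% and 16.9%). The 2 HDAC11 lists differed more (27.5% and 19.3%), so this share cannot decide. The labels of HDAC6 list 1 and HDAC4a list 2, with 83.6% overlap and 37 identical intervals, are open to the same doubt, which was not tested.

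The Caudal list of 4 to 8 h embryos stood apart from the others. The antibody alone was argued against, since the adult female list, also made with anti-GFP, overlapped it 0.807-fold over 1000 placements but overlapped the 0 to 4 h list, made with another antibody, 3.17-fold, and with midpoints 1.02-fold against 8.03-fold. Background of the single 4 to 8 h library may account for part of the list. Its highest fold was 2.41 with HDAC11 list 2, above its 1.28 with the nearest Caudal list, and with midpoints it reached 9.10 with HDAC11 list 2, 7.89 with HDAC4a list 2 and 6.94 with HDAC6 list 1, against 1.48 at most with a Caudal list. A change of Caudal binding with stage, or binding shared with these deacetylases in embryos, stays open and was not tested.

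As fold over chance, the Caudal L3 list overlapped both EcR lists more than any Caudal list, with 13.4-fold as the lower value against 2.17-fold at most, but by number 29 of its 584 regions (4.97%) lay in an EcR list against 0.450% by random placement, and 150 (25.7%) in another Caudal list against 17.8%. An EcR ChIP under the Caudal label, which the track name in its header may point to, cannot be told apart from binding of both proteins to common regions, because few regions were involved and the fold stayed below the 116 between the EcR lists. Regions of high density in every library processed this way could contribute, as 22% of the 50 highest L3 regions lay in an EcR list against 3.37% of the rest (Fisher's exact test, p = 6.5e-06). Without those 50 the overlap was still 10.4-fold and 8.86-fold, so the highest regions were not its only source. Larval binding of Caudal at EcR regions stays open and was not tested.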
